A study of Homo sapiens with 86 samples.

How the data were processed

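Tumour tissue, fibroblasts sorted from tumours and fibroblasts grown from tumours were profiled by RNA sequencing in 86 samples of oral cavity squamous cell carcinoma. Per the labels, the patients received nivolumab, an antibody that blocks the PD-1 receptor on T cells, every 2 weeks for 1 month. The samples before treatment were biopsies and those after it were pieces of the resected tumour, so the kind of sample and the treatment cannot be told apart. Groups were taken from the sample titles: 4 single-cell libraries before and 4 after treatment from the same 4 patients, 28 bulk libraries before and 28 after treatment from the same 28 patients, 16 libraries of sorted cancer-associated fibroblasts (CAFs), 3 libraries of cultured CAFs named HNCAF-0/3 and 3 of cultured CAFs named HNCAF-1. The labels do not say which patients responded to the drug, whether the single-cell patients were among the bulk patients, or to which sorted subset each of the 16 libraries belonged.

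The deposited single-cell matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 3.0.2 per the file headers. The deposited bulk table holds whole-number read counts per gene symbol, and per the labels' descriptions it came from featureCounts. For the sorted and the HNCAF-0/3 libraries the deposited values are estimated counts and TPM per Ensembl gene, in files whose column names are those of salmon. For HNCAF-1 the deposited values are read counts and FPKM per Ensembl gene. The submitters' processing notes name Cell Ranger, R 3.6.1, Seurat 3.0 and the genome build hg38 for all samples. The aligner, the annotation, the strand setting and the version of featureCounts and salmon were not given in the sources used here. Reads of overlapping genes, near-identical copies and antisense partners may therefore be split or shared by the authors' counting. Gene positions are those of GENCODE v29 on GRCh38, counted from 1.

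Bulk counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with TMM normalisation, the filterByExpr filter and the patient in the model, at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are after over before treatment, and a patient with 0 counts at both times counts as neither higher nor lower. The patient numbers in the titles pair the libraries, because by the titles the 2 libraries of a number come from 1 person. Deviations from the group means over 5000 genes correlated at over 0.1 in 27 of the 28 pairs, with a median of 0.52 within pairs and −0.031 between other libraries, and the lowest pair was at −0.029. In 22 patients the library before treatment correlated best, among all libraries after treatment, with that of the same patient. Without the patient in the model, 241 genes were higher and 35 lower. A check for mixed-up samples found 1 pair whose libraries disagreed, and no 2 libraries held identical values. The main fit kept that pair, and without it 1534 genes were higher and 902 lower. For 41 gene lists fixed before the data were examined, the mean log2 CPM (prior count 2) of the members was compared within patients by a two-sided sign-flip permutation test with 100000 resamples, adjusted over the 41 lists. Bulk libraries held 12580000 to 44360000 counts, with a mean of 23260000 before and 23910000 after treatment (permutation p = 0.752).

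Single-cell barcodes were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs, which left 53936 of 59205. Doublets were scored against simulated pairs of cells from the same library, and 1997 cells (3.7%) were left out, from 0 to 5.79% per library. The remaining 51939 cells came at 956 to 13331 per library, with 4513996 to 98669984 UMIs in the library and a median of 1246 to 3755 UMIs per cell. They were clustered on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden method (leidenalg 0.10.2, python-igraph 0.11.9) at resolution 1, into 34 clusters. Clusters took the name of a cell type only from markers fixed before the data were examined, so each class name means cells like that type. The 6 clusters with leading genes of another class or markers of several classes stayed unnamed. They held 12.0% of cells before and 6.54% after treatment on average, and their return to the class of their best markers was tried as an alternative. Counts were summed per library and class and tested with edgeR as for bulk, with the patient in the model, in the 8 classes with at least 20 cells in both libraries of at least 3 patients. Gene lists were tested per class with fry in limma 3.58.1. Shares of cells were compared as log2 ratios within patients by an exact two-sided sign-flip permutation test, for which the smallest possible p with 4 patients is 0.125. Intervals for shares are exact binomial at 95% and cover counting error only. Comparisons among subsets of T cells were dropped after their sub-clusters were seen to be led by keratin genes or by single libraries.

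The HNCAF-0/3 and HNCAF-1 libraries were made into tables by different pipelines, so no test was run. TPM was set beside FPKM rescaled to the same sum per library, as log2(value + 1) for genes with a mean of at least 10 in either group, after subtracting the median log2 ratio of −0.33. List medians were placed among 10000 random lists matched on mean level. The sorted libraries were summarised as the median and range of TPM.

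The bulk test was tested on simulated data made from the real means and library sizes. It recovered 60 of 100 genes changed 1.5-fold and 82 of 100 changed 2-fold, with 7 false calls. The same check per single-cell class recovered 6 to 40 of 100 genes changed 2-fold and 79 to 100 of 100 changed 4-fold, with 8 to 18 false calls.

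Alternatives set before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom, no or stricter filtering of low counts, no patient in the model, other list summaries, each single-cell patient or cultured replicate left out, doublets kept, a 10% mitochondrial limit, resolutions 0.5 and 2, at least 50 cells, and other pseudocounts, minimum levels and scalings. A further 9 alternatives were added after seeing the data: covariates for small-RNA share and for muscle, leukocyte and squamous gene levels, the removal of 3 patients with a library standing apart in mitochondrial or top-20 gene share, the removal of the pair that disagreed, the return of unnamed clusters in both single-cell analyses, and a restriction to genes whose level in the class came near that in their highest class, at 25% or more.

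Genes are named by a rule set before the data were examined. In bulk these are the 12 largest changes per direction among genes that passed, had an average log2 CPM of at least 1 and moved the same way in at least 20 patients, and up to 4 members of each list by smallest p. In each single-cell class they are up to 6 genes per direction that passed and moved the same way in every patient, or the 3 of smallest p where none passed, and up to 4 members of the T cell and CAF lists. In cultured CAFs they are the 10 largest ratios per direction and list members. Immunoglobulin and T cell receptor variable segments, mitochondrial and Y-linked genes and genes without a symbol were not named. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.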

Results

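RNA was sequenced from oral cavity squamous cell carcinomas before and after nivolumab, as dissociated single cells from 4 patients and as bulk tissue from 28 patients, each sampled at both times, by biopsy before and from the resected tumour after treatment. Fibroblasts from such tumours were sequenced after sorting (16 libraries) and after 3 passages in culture (3 libraries of HNCAF-0/3 and 3 of HNCAF-1). The series title concerns CAF subsets and the response to immunotherapy. The labels give no response, so the comparisons are of time and, without a test, of the 2 cultured groups.

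The bulk comparison asked which genes differed in the tumour between the sample before treatment and the one after it. Macrophage, T cell and fibroblast genes rose and genes of basal keratinocytes, cell division and hypoxia fell. Of 23844 genes, 1716 were higher and 985 lower after treatment by edgeR's quasi-likelihood test. SFRP4, a secreted modulator of Wnt signalling on chromosome 7 (37905932 to 38025695), rose by a log2 fold change of 2.24 ± 0.57 (SE, n = 28 patients, higher in 22, adjusted p = 0.0135). Its mean level went from 4.48 ± 9.504 to 34.4 ± 99.1 CPM (SD). The matricellular proteins CTGF (chromosome 6, 131948176 to 131951373) and CYR61 rose by 1.77 ± 0.28 and 1.38 ± 0.28 on the log2 scale, and CTGF went from 41.8 to 134 CPM.

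Among the other largest rises were PDK4, a kinase that inhibits pyruvate dehydrogenase (2.03 ± 0.40, adjusted p = 0.00304), ZBTB16, a zinc finger transcription factor (1.89 ± 0.39), and TSC22D3, the glucocorticoid-induced leucine zipper (1.51 ± 0.26). RGS1, a regulator of G protein signalling abundant in lymphocytes, rose by 1.42 ± 0.24 and was higher in 25 of 28 patients. GPC6, a glypican, ITGBL1, DACT1, CHRNA1, a subunit of the muscle acetylcholine receptor, and the microRNA gene MIR5690 rose by 1.52, 1.41, 1.39, 1.55 and 1.94. MIR5690 lies inside FKBP5 on the same strand, so its counts may hold reads of that gene.

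KRT15, a keratin of basal keratinocytes on chromosome 17 (41513743 to 41522529), fell by 1.61 ± 0.37 on the log2 scale (lower in 21 of 28 patients, adjusted p = 0.0081), with mean levels of 1285 ± 891.8 CPM before and 694 ± 770.3 CPM after treatment. DMP1 and DSPP, matrix proteins of dentin and bone, fell by 1.76 ± 0.45 and 1.51 ± 0.42. The other largest decreases were those of OFCC1 (−1.70), MAP7D2 (−1.41), the GABA receptor subunit GABRQ (−1.38), ZNF541 (−1.37), LINC00491 (−1.27), the lactate transporter SLC5A12 (−1.26), WDR72 (−1.26), the potassium channel subunit KCNMB2 (−1.25) and PADI3, an enzyme of keratinocyte differentiation (−1.24). PDK4, CYR61, GABRQ, ZNF541 and SLC5A12 overlap no other annotated gene, and the other genes above overlap at least 1.

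Among immune lists, those of macrophages, MHC class II and T cells other than regulatory T cells rose. The regulatory T cell, B cell, plasma cell, NK cell, dendritic cell, mast cell and neutrophil lists did not pass, as given below. The macrophage list rose by a mean of 0.83 ± 0.79 log2 CPM (SD, n = 28, higher in 26 patients, permutation adjusted p = 0.00041, the smallest that the resamples can give). Of its 11 measured members 10 rose, and 11 when adjusted over the list alone. The scavenger receptor CD163 rose by 1.20 ± 0.19, MS4A7 by 1.01 ± 0.13, the mannose receptor MRC1 by 1.08 ± 0.20 and the complement component C1QA by 0.88 ± 0.18. The T cell exhaustion and checkpoint list rose by 0.63 ± 0.74 (24 patients, permutation adjusted p = 0.00103), with 8 of 14 members higher and 11 adjusted over the list alone. PDCD1, which encodes the PD-1 receptor (chromosome 2, 241849881 to 241858908), rose by 1.08 ± 0.18 in 26 of 28 patients, from 5.35 to 11.6 CPM. HAVCR2 (TIM-3) rose by 0.77, the ectonucleotidase ENTPD1 by 0.52 and the PD-1 ligand PDCD1LG2 by 0.66.

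The cytotoxic list rose by 0.75 ± 1.12 (21 patients, permutation adjusted p = 0.00779), with 9 of 15 members higher and 11 adjusted over the list alone, among them GZMK by 1.27 ± 0.30, PRF1, which encodes perforin, by 0.97 ± 0.24 and KLRD1 by 0.98 ± 0.18. T cell identity genes rose by 0.70 ± 1.08 (18 patients, permutation adjusted p = 0.00756), with 9 of 14 members higher and 13 adjusted over the list alone, including ZAP70, a kinase of T cell receptor signalling, by 0.78 ± 0.23. Resident memory genes rose by 0.55 ± 0.79 (23 patients, permutation adjusted p = 0.00756), with 6 of 9 members higher and 6 adjusted over the list alone, including the chemokine receptor CXCR6 by 0.82. Naive and central memory genes rose by 0.50 ± 1.05 (18 patients, permutation adjusted p = 0.0497), with 3 of 8 members higher under either adjustment, among them IL7R by 0.92 and KLF2 by 0.93. MHC class II genes rose by 0.51 ± 0.75 (22 patients, permutation adjusted p = 0.00656), with 6 of 8 members higher and 7 adjusted over the list alone, including HLA-DRA by 0.57 ± 0.14. The mean of 10 pan-leukocyte genes was itself higher by 0.63 ± 0.84 in 20 of 28 patients (permutation p = 0.00041). With that mean as a covariate, 2 genes were higher and 1 lower at an adjusted p under 0.05 and 2372 genes were at an unadjusted p under 0.05.

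Fibroblast lists rose as well. Myofibroblastic CAF and matrix genes rose by 0.89 ± 1.40 (21 patients, permutation adjusted p = 0.00899), with 10 of 16 members higher and 15 adjusted over the list alone. LRRC15, a membrane protein of myofibroblastic CAFs, rose by 1.25 ± 0.34, the contractile genes TAGLN and ACTA2 by 1.05 ± 0.22 and 0.83 ± 0.22, and CTHRC1 by 0.71 ± 0.21. Fibroblast identity genes rose by 0.51 ± 0.80 (23 patients, permutation adjusted p = 0.00899), with 8 of 14 members higher and 12 adjusted over the list alone. The proteoglycan DCN rose by 0.97 ± 0.20 in 26 of 28 patients, from 222 to 447 CPM, and LUM by 0.80 ± 0.21. TGF-beta response genes rose by 0.45 ± 0.68 (22 patients, permutation adjusted p = 0.00899), with 3 of 11 members higher and 4 adjusted over the list alone. Genes used to sort CAFs rose by 0.50 ± 0.68 (23 patients, permutation adjusted p = 0.00523), with 5 of 9 members higher and 8 adjusted over the list alone, including THY1 by 0.62 ± 0.15 and PDGFRB by 0.59 ± 0.18. All 9 are also members of the myofibroblastic or the fibroblast identity list, so this list adds no further genes. The inflammatory CAF list was at 0.67 ± 1.53 (19 patients, permutation adjusted p = 0.0571) and did not pass, although its members CXCL12, DPT and HAS1 rose by 0.87, 1.22 and 1.18.

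Basal keratinocyte and squamous carcinoma genes fell by 0.79 ± 1.37 (higher in 6 of 28 patients, permutation adjusted p = 0.00437), with 5 of 14 members lower and 9 adjusted over the list alone. Besides KRT15, the log2 fold changes were −0.71 ± 0.18 for the growth factor receptor EGFR, −0.74 ± 0.19 for the hemidesmosome integrin ITGB4 and −0.80 ± 0.21 for TP63, a transcription factor of squamous cells. Cell cycle genes fell by 0.56 ± 1.03 (higher in 9 patients, permutation adjusted p = 0.0123), with 4 of 15 members lower and 13 adjusted over the list alone. The mitotic kinase PLK1 was at −0.53, BIRC5 at −0.66, MCM2 at −0.64 and the thymidylate synthase gene TYMS at −0.53. Hypoxia and glycolysis genes fell by 0.37 ± 0.59 (higher in 9 patients, permutation adjusted p = 0.00899), with 2 of 14 members lower and 3 adjusted over the list alone, the glucose transporter gene SLC2A1 at −0.98 ± 0.24 and VEGFA at −0.58 ± 0.18. With the squamous gene level as a covariate, 155 genes were higher and 29 lower.

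The remaining lists did not pass. Type I interferon response genes were at −0.60 ± 1.36 (higher in 11 of 28 patients, permutation adjusted p = 0.0571), with 0 of 15 members past the threshold in edgeR. IFIT1 was at −0.98 ± 0.33 with an adjusted p of 0.0526. Regulatory T cell genes were at 0.28 ± 0.62 (0.0571), endothelial genes at 0.33 ± 0.72 (0.0507), plasma cell genes at 0.58 ± 1.68 (0.159), tertiary lymphoid structure chemokines at 0.37 ± 1.11 (0.168), B cell genes at 0.47 ± 1.97 (0.288) and interferon gamma response genes at 0.18 ± 1.16 (0.516), the bracketed values being permutation adjusted p. The chemokine CXCL13 was at 0.82 ± 0.35 with an adjusted p of 0.117. NK cell genes went both ways, with KLRC1 higher by 0.71 and S1PR5 at −0.89, and so did pericyte and smooth muscle genes, with CNN1 higher by 1.36, RGS5 by 0.55 and NOTCH3 at −0.57. The permutation adjusted p was 0.183 for NK cell, 0.168 for pericyte, 0.168 for mast cell and for MHC class I, 0.172 for lymphatic endothelial, 0.159 for heat shock, 0.241 for salivary gland, 0.252 for adipocyte, 0.27 for immediate early and 0.288 for ribosomal protein genes. It was 0.471 for haemoglobin, 0.515 for keratinisation, 0.572 for nerve and for mitochondrial genes, 0.713 for partial EMT, 0.737 for skeletal muscle, 0.784 for housekeeping, 0.872 for dendritic cell and 0.899 for neutrophil genes. TTN, a muscle gene, averaged 1310 CPM before and 11970 ± 60460 CPM (SD) after treatment with 17 of 28 patients higher.

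**Figure D1:**
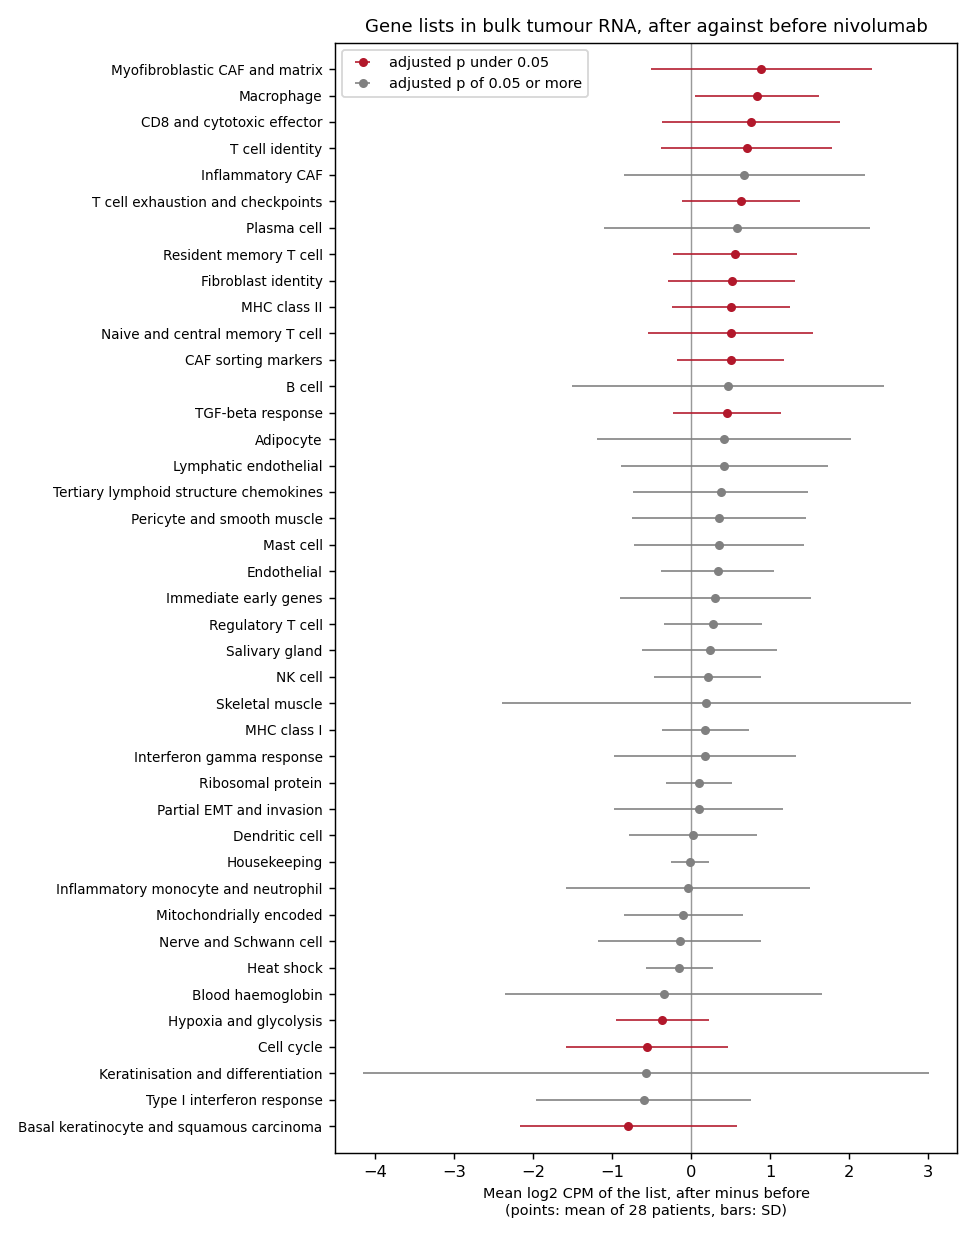
Mean log2 CPM of each of 41 gene lists after minus before nivolumab in bulk tumour tissue, as the mean (point) and SD (bar) over 28 patients, in red where the permutation adjusted p was under 0.05. The 11 red lists above 0 include macrophage genes at 0.83 and the 3 below 0 include basal keratinocyte genes at −0.79.

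The test kept the comparison within patients, and without the patient in the model 241 genes were higher and 35 lower, with 1 list higher and 0 lower. DESeq2 called 2797 and 1718 genes, and without 3 patients who had a library standing apart 1209 and 400 genes were called.

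In the single-cell libraries the comparison asked how the makeup of the tumour and each cell class differed with time in 4 patients. Plasma cells, which secrete antibodies, made up 0.83% ± 0.60 of cells before and 3.29% ± 2.42 after treatment (SD, n = 4), and were higher in 4 of 4 patients with a mean log2 ratio of 1.94 ± 0.58, which gives the smallest p that an exact sign-flip test of 4 patients can reach. Endothelial cells were at 13.0% ± 5.7 and 7.16% ± 2.55, lower in all 4 patients (log2 ratio −0.85 ± 0.72, the same smallest exact p), but with called doublets kept they were higher in 1 of 4 (exact p = 0.25). T cells were at 13.3% ± 8.1 and 28.9% ± 18.2, higher in 3 of 4 patients (log2 ratio 0.94, exact p = 0.375). Without patient 1 they were at 16.0% and 23.4% (log2 ratio 0.20), and as a share of cells outside the epithelial class they were higher in 4 of 4 patients (0.87, the smallest exact p). In the patient with the widest difference T cells went from 5.07% (exact 95% interval 4.68 to 5.48) to 45.3% (44.5 to 46.2). Epithelial cells were at 33.4% ± 19.3 and 22.3% ± 35.5, higher in 1 of 4 patients (exact p = 0.25), and without patient 4 they were at 26.6% and 4.55%, higher in 0 of 3. Pericytes were at 4.76% and 2.21% (log2 ratio −1.32, higher in 1 of 4, exact p = 0.25), and as a share of cells outside the epithelial class they were lower in all 4 (−1.40, the smallest exact p).

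Monocytes and macrophages were at 7.03% before and 9.95% after treatment, fibroblasts at 7.00% and 10.1%, NK cells at 3.51% and 3.18%, B cells at 1.11% and 2.17%, dendritic cells at 2.63% and 2.14%, mast cells at 0.57% and 0.93%, plasmacytoid dendritic cells at 0.30% and 0.41%, skeletal muscle at 0.47% and 0.69%, and unnamed clusters at 12.0% and 6.54%. With 4 patients no share can pass 0.05 in this exact test. Dissociation and the kind of sample, biopsy or resection, can set such shares.

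**Figure D2:**
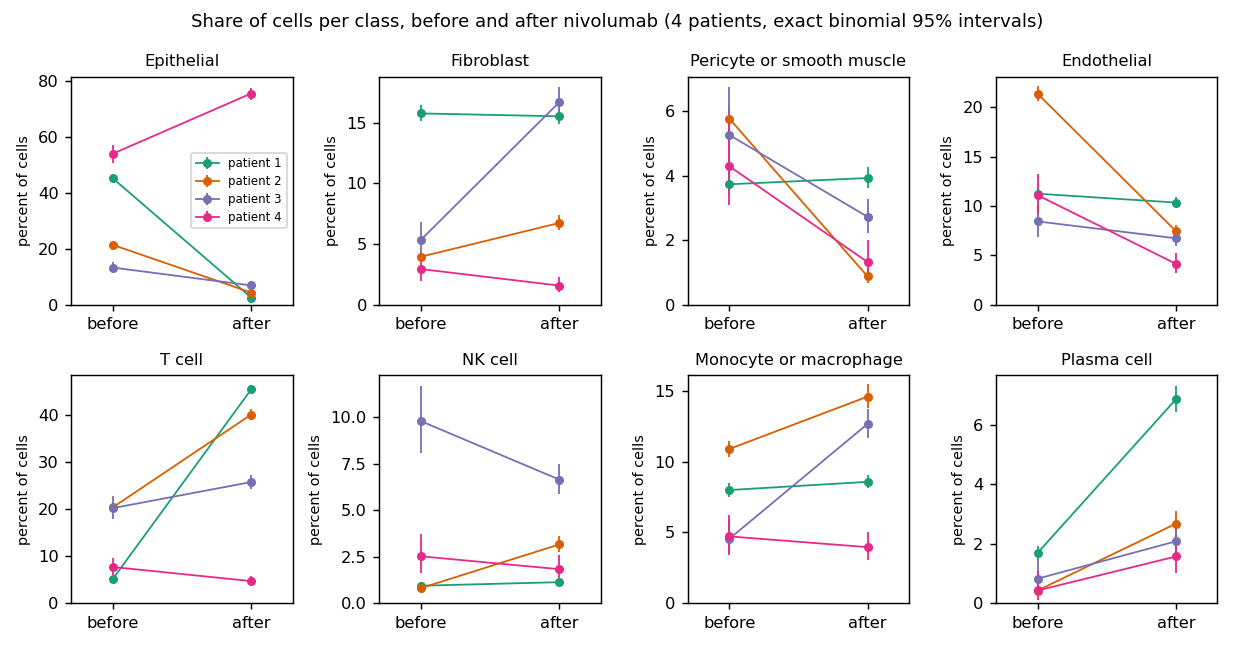
Percent of cells in 8 classes in each of 4 patients before and after nivolumab, with exact binomial 95% intervals, each line joining the 2 libraries of 1 patient. Plasma cells were higher after treatment in all 4 patients (0.83% and 3.29% on average), and endothelial cells were lower in all 4 (13.0% and 7.16%).

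Within classes the genes called higher were mostly immunoglobulin genes, and the 6 calls lower, in 3 of 8 classes, were genes highest in epithelial cells. In T cells IGLC2, which encodes a constant region of antibody light chains, rose by 4.81 ± 0.61 on the log2 scale (SE, 4 of 4 patients, edgeR adjusted p = 0.0237), from 52.2 ± 39.7 to 3426 ± 5404 CPM (SD), and IGKC and IGHG3 rose by 2.54 and 3.22. JCHAIN, the joining chain of secreted antibodies, passed in T cells at 3.60 ± 0.38 with 3 of 4 patients higher and the other at 0 both times. The epithelial gene CALML3 fell in T cells, at −2.63 ± 0.39, as did the metallothionein MT1X at −1.78 ± 0.24. In monocytes and macrophages IGHG2 rose by 4.82 ± 0.55, and the epithelial genes FXYD3 and KRT15 were lower, at −3.76 ± 0.42 and −5.62 ± 0.65. IGHG3, IGHG1 and IGKC rose in dendritic cells by 6.26, 3.59 and 2.41 in 3 patients, IGLC2 and IGHA1 in NK cells by 4.84 and 1.87, and HBB, a globin of red cells, in endothelial cells by 7.52 ± 0.36, while KRT6B fell in pericytes, at −2.57 ± 0.39. Over the 8 classes 15 calls were higher and 6 lower of 63231 pairs of gene and class, and 2826 pairs were at an unadjusted p under 0.05. The only call in fibroblasts was IGHM, at 7.15 ± 0.47 with 3 of 4 patients higher and the other at 0 both times, and it was not called without any 1 of the patients. The fit in dendritic cells never held patient 4, so its 3 calls could not change when that patient was left out. Without patients 1, 2, 3 and 4 in turn, 11, 13, 16 and 12 of the 21 calls stayed. None was made in endothelial cells without patient 1 or 2, in dendritic cells or pericytes without patient 1, in NK cells without patient 2 and in monocytes and macrophages without patient 3 or 4, and none was lower in pericytes without patient 4. Without patient 2 none was lower in T cells, where the calls of CALML3 and MT1X ended. Without the same patient none was higher in monocytes and macrophages, where the call of IGHG2 ended. JCHAIN in T cells and IGHM in fibroblasts were chosen after their values were seen. The called gene was highest in plasma cells in 14 of these 21 calls, in epithelial cells in 6 and, for HBB, in the skeletal muscle class. In 20 of the 21 its level in the class was under 0.1 of that in its highest class. In T cells the summed immunoglobulin constant genes went from 72.0, 30.04, 3.68 and 1.17 per 10000 UMIs before to 466, 62.5, 44.8 and 33.7 after treatment in the 4 patients, beside 4693 to 6152 in plasma cells.

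In epithelial cells edgeR called 0 genes, with 528 at an unadjusted p under 0.05, and DESeq2 called 10 higher and 1 lower. The smallest p values there were those of IGHG1 (4.91 ± 0.50, adjusted p = 0.0598), IGHM (7.00), IGLC2 (3.99), LTF (−3.43), MSMB (−3.15) and PTGS1 (−1.12). Over all classes edgeR without the patient in the model called 0 pairs of gene and class, with 1195 at an unadjusted p under 0.05, and DESeq2 called 60 higher and 51 lower. Without patient 3 edgeR called 34 higher and 80 lower, without patient 4 it called 18 and 10, and at clustering resolution 0.5 it called 6 and 3.

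No gene of the checkpoint and cytotoxic lists passed in T cells. CXCL13, a B cell chemoattractant, was at 1.76 ± 0.62 (4 of 4 patients, edgeR adjusted p = 0.493), PDCD1 at 0.56 ± 0.21 (4 of 4, 0.534), TOX at 0.57, IFNG at 0.92, GZMK at 0.82 and GZMH at 0.79, while TIGIT was at −0.42 (higher in 0 of 4). The cluster of T cells led by KLRC2, GNLY and CXCL13 came mostly from patient 1 after treatment. In fibroblasts LRRC15 was at 1.29 ± 0.67 (3 of 4 patients), ACTA2 at −0.59 ± 0.34, MMP11 at −0.38, IGF1 at −1, APOD at −1.02, PLA2G2A at −1.65 ± 1.71 and FAP at −0.094, all with an edgeR adjusted p of 0.9999. Fibroblasts of patient 1 fell mostly into a cluster led by PRG4 and PLA2G2A before and into one led by SFRP4 and OMD after treatment, and those of patients 2, 3 and 4 mostly into one led by MMP3 and MMP1. When fibroblasts were clustered alone, 92.1% of those of patient 2 before treatment lay in a group led by FABP4 and ADAM12, and 90.4% of those after treatment lay in a group led by MMP1 and MMP3. That group held 83.1% of 59 and 93.6% of 652 fibroblasts of patient 3 before and after treatment, and 64.3% of 28 and 80.0% of 25 of patient 4. The libraries were clustered without a correction for differences between them, and several other groups came almost wholly from 1 library. A shift between groups can therefore not be told apart from a difference between libraries.

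Of the gene lists tested per class with fry, 1 rose, the plasma cell list in epithelial cells (2.32 ± 0.19, SD, 4 of 4 patients, fry adjusted p = 0.0182), and none fell. Its member IGHG1 was at 77.9 CPM in the pooled epithelial cells beside 53630 CPM in plasma cells. RNA freed from plasma cells is therefore a candidate source, and expression by the epithelial cells was not tested apart from it. In epithelial cells 1 list was called higher without patient 1, and none without patients 2, 3 and 4 (smallest fry adjusted p 0.136, 0.199 and 0.0770) or with doublets kept. In other classes 3, 3 and 2 lists were called higher without patients 1, 3 and 4. MHC class II genes in T cells were at 0.54 ± 0.22 (4 of 4 patients, fry adjusted p = 0.109), with 8 of 9 members higher adjusted over the list alone. Expression of these genes by the T cells was not tested apart from free RNA of other classes. Myofibroblastic CAF genes in fibroblasts were at 0.27 ± 0.81 and inflammatory CAF genes at −0.37 ± 1.71 (fry adjusted p = 0.85 for both).

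The 2 cultured CAF groups, whose names the labels do not explain, were set side by side. Cell cycle genes stood higher in HNCAF-0/3, with 14 of 15 members above HNCAF-1 in all 3 replicates and a median centred log2 ratio of 2.83, at percentile 100 of random lists. The proliferation marker MKI67 was at 14.7 ± 5.7 TPM in HNCAF-0/3 and 1.03 ± 0.74 rescaled FPKM in HNCAF-1 (SD, n = 3), and RRM2 and CDK1 had centred log2 ratios of 5.21 and 4.08. The calcium-binding protein gene S100A4 was at 4310 ± 1266 and 129 ± 88 on the common scale, and the collagenase MMP1 at 2743 ± 2158 and 5.29 ± 8.23. COL1A1 was higher in HNCAF-1, at 9450 ± 5581 against 1068 ± 578, as were COL3A1 (−2.79), COL1A2 (−2.17) and fibronectin, FN1 (−2.17), while COL10A1 was higher in HNCAF-0/3 (3.83) and COL11A1 overlapped (−0.68). The complement gene C3 was higher in HNCAF-1 too, at 247 ± 350 against 1.55 ± 2.07 (ratio −6.27, and −3.68 without replicate 2 of each group), as was APOD, at 221 ± 202 against 15.1 ± 10.2 (−3.45), whereas POSTN (3.41), ACTA2 (2.05) and TAGLN (2.02) were higher in HNCAF-0/3.

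Across lists, CAF sorting markers had a median centred ratio of 1.02, with THY1 at 1.74, CAV1 at 1.02 and PDGFRB at −2.07. Type I interferon genes were at 1.12, with all 9 measured members overlapping between the groups. Myofibroblastic genes were at −0.44, with 5 members higher in each group, and fibroblast identity genes at −0.022. Inflammatory CAF genes were at −1.58 (7 of 14 members at the minimum level) and pericyte genes at −2.33 (4 of 10). Without replicate 2 of each group, however, these medians were 0.11 and 1.17. Of the members measured, 3 and 1 were higher in all HNCAF-1 libraries and 1 and 0 in all HNCAF-0/3 libraries. Of 9608 genes, 2907 were higher in all 3 HNCAF-0/3 libraries and 1943 in all 3 HNCAF-1 libraries, together 50.5% where chance gives 10%. Without replicate 1 of each group, where fewer libraries must separate, the HNCAF-1 count was 3287. Among the 9608 genes, 27 such as EEF1G and RN7SL1 were listed at 0 in all HNCAF-1 libraries, and another gene overlaps 25 of them. The groups came from different pipelines, so pipeline and group cannot be told apart, and totals were 36232477 to 46054902 estimated counts in HNCAF-0/3 and 12717528 to 17784575 counts in HNCAF-1.

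Most sorted libraries carried fibroblast genes, at levels that spread widely. COL1A1 reached 1 TPM in 14 of 16 libraries, and FAP and PDGFRB in 12. The fibroblast identity list had a median mean log2(TPM + 1) of 6.34, from 0.567 in the lowest library to 8.76 in the highest. After removal of mitochondrial and ribosomal protein genes and rescaling, COL1A1 reached 1 in 16 of 16 libraries, PDGFRB in 14 and FAP in 12. The fibroblast identity list then ran from 1.95 to 9.57. Over 16 libraries the median was 697 TPM for COL1A1 (0.45 to 7027), 1432 for SPARC (3.96 to 6105), 238 for FN1 (0.23 to 2416), 158 for PDGFRB (0 to 583), 88.5 for ACTA2 (0 to 1061) and 7.19 for FAP (0 to 157). Genes of other cells were present too. Medians were 28.8 TPM for KRT14 (up to 2411), 20.2 for KRT5 (up to 1293) and 8.33 for the pericyte gene RGS5 (up to 698). KRT14 and KRT5 had medians above that of FAP and reached 1 TPM in 15 of 16 libraries. Without mitochondrial and ribosomal protein genes RGS5 was at 20.55 and FAP at 20.58. EPCAM at 0.35 (up to 10.3), PTPRC at 1.51 (up to 69.0) and PECAM1 at 1.38 (up to 11.8) had medians below that of FAP. CD68, a gene of the macrophage list, lay above FAP at 12.5 (up to 29.3) and reached 1 TPM in 15 of 16 libraries. The whole macrophage list had a median mean log2(TPM + 1) of 0.88. Mitochondrial genes took 37.2% to 96.1% of TPM, and 7432 to 38889 genes were detected from 8227991 to 32554259 estimated counts. Correlations between libraries ran from 0.21 to 0.90 across genes, and genes are not independent replicates.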

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

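The tests of sample splits and of free RNA from other classes were chosen after the result was seen, and the test of immunoglobulin ratios was written before. Among 120 groups of 4 libraries, 16 held a library far from the other 3, and chance gives about 5% of groups of normally distributed, independent values. These groups share the same libraries and their values were not shown to be normal, so the 16 are not read as an excess. Of the 16, 1 is not reported here.

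The genes called between times in the single-cell classes were mostly immunoglobulin and keratinocyte genes in cells of other types. Free RNA from lysed cells, captured with the cells of other classes, is a candidate explanation, since 20 of 21 calls lay under 0.1 of another class's level, with a median of 0.025, against 4.73% of all tested pairs. Whether the immunoglobulins came from plasma cells of the same library stays open: the ratio of IGHA1 to IGHG3 in T cells and in plasma cells gave a Spearman rho of 0.619 over 8 libraries (exact p = 0.115; Pearson r = 0.85, exact p = 0.0272), and r was −0.24 without the 2 farthest libraries, on which the relation rests. The real order of the samples gave 21 calls and the highest other split 16, but 8 splits are too few for a share under 0.05, the real one being 1 of them. A biological change of expression within these classes was not tested apart from free RNA, whose source also differed with time, plasma cells being more frequent in the samples after treatment.

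Several immunoglobulin values of patient 1 stood apart from those of the other 3 patients at the same time. In T cells after treatment these were IGLC2 at 11500 CPM (others 191 to 1431), IGKC at 39330 (338 to 4438) and IGHG3 at 22050 (16.4 to 372), and IGHG3 before treatment was at 1184 (0 to 72.0). In epithelial cells of that patient IGHM was at 5.57 CPM before (0 to 0.64) and 1078 after treatment (0 to 8.19), and IGLC2 was at 79.7 before (12.8 to 20.8). IGHG2 in monocytes and macrophages of patient 2 after treatment was at 879 CPM (12.2 to 139).

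Epithelial cells made up 75.5% of cells in patient 4 after treatment (others 2.51% to 6.85%). Unnamed clusters held 25.5% of cells in patient 3 before treatment (5.96% to 9.17%). Among fibroblast genes, LRRC15 was at 122 CPM in patient 2 before treatment (8.64 to 23.6), IGF1 at 75.7 in patient 1 after it (0 to 7.79), PLA2G2A at 2942 in patient 1 before it (0 to 107) and PDGFRA at 278 in patient 4 before it (95.4 to 111). KRT15 in monocytes and macrophages of patient 3 before treatment was at 307 CPM (7.05 to 41.4).

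Of the gene lists tested per class, 1 was called in the real order of the samples and 2 in the highest other split, 5 of the 8 splits giving as many, and 8 splits are too few for a share under 0.05. The list called was that of plasma cells in epithelial cells, for which free RNA is a candidate explanation too and was not tested.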

How the results depend on the processing

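The covariates, the samples left out after a check, the return of unnamed clusters and the restriction to genes near their highest class were chosen after seeing the data. In bulk, DESeq2 called 2797 genes higher and 1718 lower against 1716 and 985. The fit without the patient called 241 and 35, the leukocyte covariate left 2 and 1, the squamous covariate 155 and 29, no filter gave 529 lower, and 400 were lower without the 3 patients standing apart, a fit that also has fewer samples. The causes of the other shifts were not tested. Of the 14 lists called, 1 higher and 0 lower passed without pairing within patients. Over all settings and named genes in bulk, 1861 values kept their side of the threshold, 293 lost the call and 65 gained it. Changes of sign between values that both missed the threshold are held in the 1861 and were not counted. With a call in the main or the alternative fit, 2 values turned sign. TNNI2 (3.57) did so without the patient. The other change of sign came with the leukocyte covariate, in a bulk gene: CD3G was at −0.0117. For single lists 187 values kept their side, 15 lost it and 3 gained it.

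In single cells, 15 calls higher and 6 lower became 60 and 51 with DESeq2, 0 and 0 without the patient, 568 and 649 with no filter, 6 and 3 at resolution 0.5, and 0 and 0 among genes at 25% or more of their highest class. With single patients left out they ranged from 16 to 34 higher and from 6 to 80 lower, the extremes of 34 and 80 being without patient 3, and 11 to 16 of the 21 calls stayed. The 1 list higher became 0 with doublets kept and 0 without the patient, where 1 was lower, and 0 to 4 with single patients left out, of which 0 to 1 in epithelial cells. Among named genes 546 values kept their side, 53 lost it and 18 gained it. All 140 mean log2 ratios of shares under the alternatives stayed within 1 SD over the patients. Leaving out 1 of 4 patients cannot move a mean by that much, so those settings could not show a shift. The causes were not tested.

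In cultured CAFs, the inflammatory CAF median ranged from −2.06 to 0.11 and the pericyte median from −2.76 to 1.17 with single replicates left out. At minimum level 1, 5407 genes were higher in HNCAF-0/3, where more genes enter, and with single replicates left out 2684 to 3287 were higher in HNCAF-1 and 3183 to 3799 in HNCAF-0/3, where fewer libraries must separate. Of gene ratios 399 stayed within 1 SD and 57 did not, and of list ratios 129 and 8. Sorted lists stayed within 1 SD in 67 values and moved in 13. A 2-fold change within a single-cell class can be missed at this number of patients and cells, since 6 to 40 of 100 simulated ones were recovered per class.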

Other observations

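The tests of bulk sample splits, squamous share, small-RNA share and leukocyte content were chosen after the result was seen, and both glucocorticoid predictions were written before their values were computed, though FKBP5 had been seen leading a group of T cells.

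Type I interferon response genes had lower means after treatment in each of the 8 single-cell classes, none past the threshold. The mean difference was −1.30 ± 0.83 log2 (SD, 0 of 4 patients higher, fry adjusted p = 0.362) in endothelial cells, with 13 of 15 members lower adjusted over the list alone. It was −1.37 ± 0.84 in NK cells (0 of 4, fry adjusted p = 0.29), −1.14 ± 1.03 in monocytes and macrophages (0 of 4, fry adjusted p = 0.626), −1.35 ± 1.57 in T cells, −1.30 ± 1.68 in epithelial cells, −0.99 ± 1.27 in fibroblasts and −0.99 ± 0.78 in pericytes, each higher in 1 of 4, and −1.37 ± 1.15 in dendritic cells (0 of 3). In bulk the list was at −0.60 (permutation adjusted p = 0.0571). MHC class II genes were at 1.11 ± 0.94 in pericytes (4 of 4 patients, fry adjusted p = 0.502) and at 1.06 ± 1.22 in fibroblasts (3 of 4, 0.443), but at −0.50 ± 1.25 in endothelial cells (2 of 4), −0.29 ± 0.76 in NK cells (2 of 4), 0.0025 ± 0.18 in dendritic cells (1 of 3), 0.24 ± 1.24 in epithelial cells (2 of 4) and 0.40 ± 0.53 in monocytes and macrophages (3 of 4). Expression of MHC class II genes by each class was not tested apart from free RNA of other classes.

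The sorted libraries, whose subsets the labels do not give, each held a value of every list. Single libraries reached a mean log2(TPM + 1) of 8.53 for mast cell genes (median 0.35), 8.63 for haemoglobin (0.56), 4.67 for skeletal muscle (0.70), 8.46 for basal keratinocyte (2.74) and 6.70 for plasma cell genes (2.08).

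More genes were higher than lower after treatment in bulk, led by macrophage, T cell and fibroblast genes. Chance is an unlikely cause, since 1 of 100 splits, the real one, called as many genes by limma-voom (3324, the highest other 1). That is the smallest share that 100 splits can give. Each other split swapped 14 patients, which moves the real difference into the spread and can lower its count. As the whole cause, a lower share of squamous cells would raise other cell types alike. The macrophage list rose more than the mean of 12 other non-squamous lists, by 0.594 ± 0.786 (SD, 23 of 28 patients, permutation p = 0.00045, and 0.0024 against the largest of 13 lists). However, the prior count shrinks differences at low levels. Before treatment macrophage genes averaged 4.20 log2 CPM, and among cell-type lists nerve genes averaged 0.40 and NK cell genes 1.03. Lists at such low levels may rise less in this measure under a lower squamous share alone. The comparison therefore cannot decide whether that share was the whole cause. Squamous share stays open as the whole or a part of the cause. With the squamous gene level as a covariate 6.29% of calls stayed. The median log2 fold change went from 0.58 to 0.42 for genes called higher and from −0.53 to −0.34 for genes called lower. The small-RNA share differed between times by 0.19 ± 2.80 percentage points (SD, 18 of 28 patients higher, permutation p = 0.718). It stays open, since a p above the threshold does not show equal shares, and 90.8% of calls stayed with it as a covariate that moved the median by less than its SE (0.58 both times). The leukocyte content of the tissue piece remains a candidate explanation, since 0.07% of calls stayed with it as a covariate, the median log2 fold change of genes called higher going from 0.58 to 0.29 and its median SE from 0.151 to 0.166, so that these calls ended mostly because the folds shrank. Genes called lower went from −0.53 to −0.363. Whether that content differed through infiltration during treatment or through which piece was taken, biopsy or resection, stays open.

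TSC22D3, ZBTB16 and PDK4, which glucocorticoids induce, were among the largest rises in bulk. Glucocorticoid exposure at the time of the second sample is a hypothesis consistent with 10 other targets, whose mean rose by 0.495 ± 0.616 (SD, 25 of 28 patients, permutation p = 0.00035, percentile 100 of 10000 matched random lists, 1 list tested), and by 0.431 without FKBP5 (permutation p = 0.00117). FKBP5 rose by 1.03 ± 0.24, KLF9 by 1.07 ± 0.19, PER1 by 0.80 and CRISPLD2 by 0.72, while SGK1 was at −0.003 and MAOA at −0.50 without passing. With the level of 10 pan-leukocyte genes as a covariate, the median of the 3 genes went from 1.893 to 1.594, so most of the rise stayed. None of the 3 then passed (edgeR adjusted p 0.173 to 0.277). That covariate measures leukocyte content only in part, so content cannot be excluded as the cause. Within classes glucocorticoid exposure stays open. In the 3 classes that the prediction named, the measured targets and those of the 3 genes measured (1, 2 and 1) together averaged 0.471 in T cells, 0.599 in endothelial cells and 0.927 in fibroblasts (4 of 4 patients each). The targets alone were at 0.798 with 3 of 4 higher in fibroblasts. The measured ones of the 3 genes were higher in 3 of 4 in T cells and in endothelial cells. Read strictly, the prediction needed every patient for each set. In classes outside it, the joint mean was 0.047 ± 1.38 (SD) in pericytes, 0.602 in monocytes and macrophages and 0.50 in epithelial cells (3 of 4 each). It was 0.910 in NK cells (4 of 4) and 0.372 in dendritic cells (3 of 3).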
